A study of Gallus gallus with 2 samples.

How the data were processed

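Breast muscle RNA was sequenced from 2 chicken strains at 7 weeks of age, White Recessive Rock (WRR, labelled fast-growing) and Xing Hua (XH, a Chinese native strain labelled slow-growing). Per the labels' protocols, RNA of 4 hens of each strain was pooled in equal amounts and depleted of ribosomal RNA. Also per the labels' protocols, 1 library per strain, strand-marked by the dUTP method, was sequenced on an Illumina HiSeq instrument. The labels give a body weight of 625.3 ± 12.0 g for the WRR birds and 328.5 ± 10.6 g for the XH birds, without naming the kind of error. There was thus 1 library per strain and no replicate. No spread between birds could be estimated, no p-value is given, and every difference described is one between 2 pooled libraries.

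A table of 21993 long non-coding RNA (lncRNA) transcripts was used. By its deposited name it is limited to newly found lncRNAs, so lncRNAs already known may be absent from it. It gives for each transcript a serial identifier, a length, an interval on the genome and 3 values per library. Per the submitters' processing notes, the build galGal4 and the tools TopHat2 2.0.8 and Cufflinks 2.0.2 were used, with no role named. How transcripts were assembled, merged between libraries and called non-coding is not given in the sources used here. The deposited counts are uniquely mapped reads per transcript, per the file headers. The deposited RPKM values (reads per kilobase of transcript per M reads) are scaled to a total that the file headers give beside each library's counts, 9442942 for WRR and 7714657 for XH. What this total counts is not stated further. The RPKM formula applied to the listed reads, length and total gave all 21449 listed WRR values and all 21697 listed XH values within 0.001% of the value. The deposited coverage is read as the percent of a transcript's length covered by reads, per the file headers, which call it coverage. A dash stands in place of all values of a library for 544 transcripts in WRR and 296 in XH. Since the smallest listed count was 1, a dash was taken as 0 reads. It entered log2 ratios as 0 RPKM plus the pseudocount, and folds against a dash were computed against a floor of 3 reads per library.

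The smallest deposited start was 0, and end minus start equalled the length for 20855 transcripts. Starts were therefore read as counted from 0 and are printed counted from 1. For 1064 transcripts the interval was longer than the transcript (gapped here). For 74 it was shorter, and these were grouped with the contiguous ones. The table holds no strand, sequence, exon structure, gene name or neighbouring gene, and no genome of this build was used here. Identifiers are not paired with gene names in the table, so transcripts are named by position. Lists of muscle, growth, metabolism and other cell type genes had been fixed for the neighbours of these transcripts, and were not run because no neighbour could be assigned. Coding potential, overlap with repeats or ribosomal RNA genes and GC content were not analysed here. Without strand, overlapping transcripts cannot be separated from antisense partners.

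From the RPKM values, log2((WRR + 0.1) / (XH + 0.1)) was computed per transcript, so that a positive value means higher in WRR. This scale understates the change of low transcripts. The filter was at least 0.5 RPKM in the higher library, which kept 21625 transcripts, and transcripts at 2-fold or more on this scale were counted in each direction. Folds of single transcripts are ratios of RPKM without the pseudocount, with an exact 95% interval from the binomial distribution of the 2 read counts (Clopper-Pearson). Shares of reads have the same kind of interval. These intervals and the floor cover counting error only, not birds, pooling or library preparation, and reads without molecular identifiers are not independent molecules. Medians over transcripts have a 95% interval from order statistics, although transcripts are not independent replicates.

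Chromosomes 1-5, 6-10, 11-28, Z, W and unplaced scaffolds were compared as classes, with scaffolds assigned to a chromosome counted with it. Classes of length, and gapped against contiguous transcripts, were compared likewise, which made 11 classes. Each class median was set among 10000 random sets of the same size, drawn with the same number of transcripts from each of 10 strata of mean RPKM. The sets were drawn from all transcripts past the filter, including those of the class. A second draw, added after the data had been seen, also matched the numbering series (described in the results) and 4 strata of length. For the length classes it matched series and expression only.

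The following were fixed before the data were examined: the measure, filter and fold, the classes by chromosome, length as a kind of class, and the rule for transcripts to name. The limits of the length classes and the split into gapped and contiguous transcripts were not part of that plan. This rule took the 8 largest log2 ratios in each direction among those with at least 1 RPKM in the higher library and reads in both. It also took the 5 with the highest mean RPKM, and the 3 highest in each library among those with a dash in the other. Its part on neighbouring genes could not be applied. Alternatives were other pseudocounts, filters and scalings, a 4-fold size, and overlapping transcripts merged into loci regardless of strand, with reads and lengths summed. Scaling by edgeR's TMM and by DESeq2's size factors, from the deposited counts, was added later, and no count model was fitted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.

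The comparison of WRR with XH was tested on simulated data, with counts drawn for 21993 transcripts at the real depths. Of 100 transcripts changed 3-fold, 94 passed the 2-fold size, as did 100 of 100 changed 6-fold. The changed transcripts were taken only from those above a minimum of summed reads. Of 21308 unchanged transcripts past the filter, 4.51% passed the 2-fold size by counting error. Counts were drawn at rates pooled over both libraries, so the median log2 ratio of unchanged transcripts was 0.0037, against -0.92 in the real data. These shares are therefore not error rates of the real comparison. The median listed transcript had 21 reads in WRR and 28 in XH. At the median length of 844 bases the floor of 3 reads was 0.376 RPKM in WRR and 0.461 RPKM in XH.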

Results

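The table listed 21993 lncRNA transcripts of chicken breast muscle, 201 to 25111 bases long with a median of 844, in 1 pooled library of the fast-growing WRR strain and 1 of the slow-growing XH strain. In WRR 1846031 reads fell on them, 19.5% of the library's total (exact 95% interval 19.5 to 19.6%). In XH the number was 1883727, or 24.4% of the total (24.4 to 24.4%). Most transcripts were of low abundance. The median RPKM was 2.73 in WRR (quartiles 1.31 and 5.26) and 4.54 in XH (2.88 and 8.55). At least 10 RPKM was reached by 2454 transcripts in WRR and 4551 in XH, and at least 100 RPKM by 135 and 143. The median coverage of a transcript's length was 80.7% in WRR and 89.7% in XH.

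The reads on the listed transcripts were concentrated in a few of them, more so in WRR. The 10 transcripts with the most reads held 29.7% of the listed reads in WRR (29.6 to 29.7%) and 11.3% in XH (11.3 to 11.4%). The transcript with the highest mean, 828 bases at chromosome 1, 100373872 to 100374699 (galGal4), had 23594 RPKM in WRR and 7878 RPKM in XH. Its log2 ratio was 1.58, and the exact 95% interval of the fold was 2.97 to 3.02. The 973-base transcript at chromosome 1, 100377687 to 100378659, had 23236 RPKM in WRR and 4299 RPKM in XH, a ratio of 5.41 (5.34 to 5.47). Next came a 208-base transcript on an unplaced scaffold, with 15375 RPKM in WRR and 9307 RPKM in XH, a ratio of 1.65 (1.62 to 1.68). A 238-base transcript at chromosome 9, 9640866 to 9641103, had 5913 RPKM in WRR and 16046 RPKM in XH, 2.71-fold higher in XH (2.66 to 2.77). Its reads covered 66.8% of its length in WRR and 95.8% in XH. A 239-base transcript at chromosome 7, 21668027 to 21668265, had 10129 RPKM in WRR and 8403 RPKM in XH, a ratio of 1.21 (1.18 to 1.23). With quantile normalization the unplaced and the chromosome 7 transcripts turned direction, to log2 ratios of -0.45 and -0.40.

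The surroundings of the most abundant transcript, 30 kb to each side, were chosen after its values had been seen. The 8 transcripts there, between 100351010 and 100399079 on chromosome 1, held 23.1% of the listed reads in WRR and 5.14% in XH, a ratio of summed reads per total of 3.59 (3.57 to 3.62). Of the 8, 4 were at least 2-fold higher in WRR. One of these, the 298-base transcript at 100351241 to 100351538, had 221 RPKM in WRR and 46.1 RPKM in XH, a ratio of 4.79 (3.90 to 5.95). The transcript at 100351010 to 100351354, whose interval overlaps that one, had a ratio of 1.02 (0.741 to 1.41). The difference was thus not shared by both entries at this place. The 234-base transcript at 100381888 to 100382121 was lower in WRR, with 55.2 RPKM in WRR and 595 RPKM in XH, 10.8-fold higher in XH (8.93 to 13.1).

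**Figure D1:**
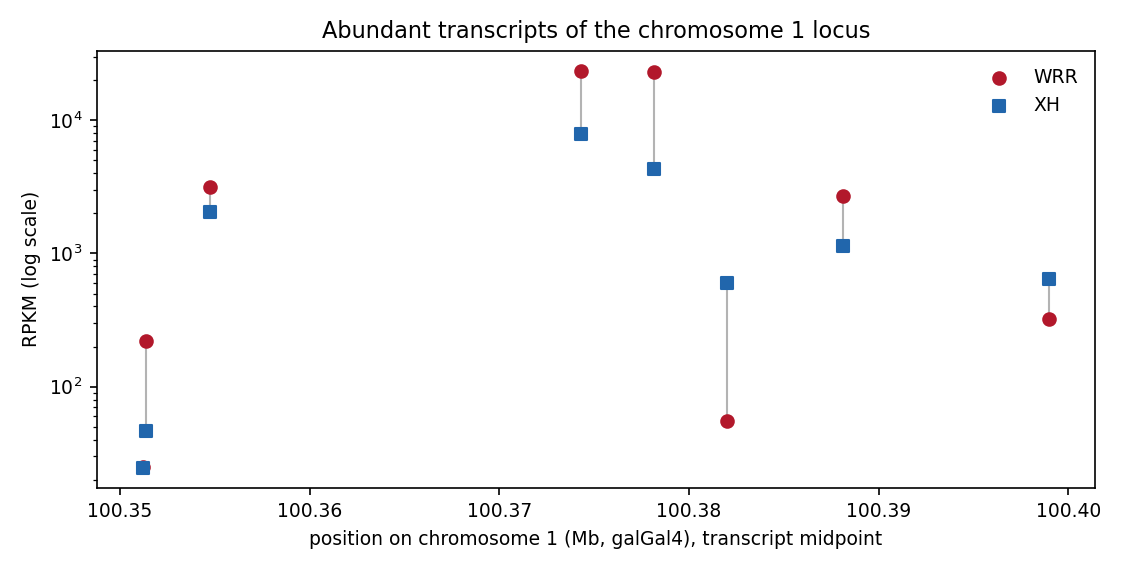
RPKM (log axis) of the 8 transcripts on chromosome 1 between 100351010 and 100399079, plotted at each transcript's midpoint (Mb, galGal4), with WRR as circles and XH as squares joined by a line, each point being 1 pooled library without error bars. The highest pair of transcripts reached 23594 and 23236 RPKM in WRR, and the transcript at 100381888 had 55.2 RPKM in WRR and 595 RPKM in XH.

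The main comparison addressed which of the listed lncRNAs of breast muscle differed between the pooled libraries of the fast-growing and the slow-growing strain. Of 21625 transcripts with at least 0.5 RPKM in the higher library, 10137 (46.9%) were at least 2-fold higher in XH, 2043 (9.45%) were at least 2-fold higher in WRR, and 9445 lay within 2-fold. The median log2 ratio of WRR over XH was -0.92 (95% interval -0.93 to -0.89), with quartiles of -1.71 and -0.043. Relative to this median, 4813 transcripts were at least 2-fold higher in WRR and 4396 in XH, so that the share of WRR among transcripts past 2-fold was 52.3% in place of 16.8%. Centring makes such a split near even by construction. Scaled to the reads listed in the table, a setting that does not, 2839 transcripts were at least 2-fold higher in WRR and 7807 in XH, a share of 26.7% for WRR. That setting gives weight to the most abundant transcripts, of which the top 10 held 29.7% of listed reads in WRR and 11.3% in XH. The exact interval of the read ratio excluded 1 for 9704 of the transcripts higher in XH and 1653 of those higher in WRR, which compares these 2 libraries and not the strains. Across transcripts, which are not replicates, the libraries correlated with Pearson's r = 0.57 on the log2 scale and Spearman's rho = 0.55.

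The direction also followed the serial numbers of the transcripts. Numbers up to 3658 (series A) ran in no order of chromosomes, numbers 3659 to 11941 (series B) ran through the chromosomes in order, and numbers 11942 to 22903 (series C) ran through them again. The order of chromosomes alone set these limits. In series A the median log2 ratio was -0.56 (95% interval -0.58 to -0.53), with 188 transcripts at least 2-fold higher in WRR and 970 in XH. In series B it was 0.057 (0.017 to 0.092), with 1775 and 1196. In series C it was -1.64 (-1.66 to -1.61), with 80 and 7971. The pooled direction thus did not hold in series B. Relative to the median of all transcripts, the medians of series A, B and C were 0.36, 0.97 and -0.72. On that scale, 733 transcripts of series A were at least 2-fold higher in WRR and 129 in XH. The direction of series A thus depends on the scaling. How the series arose is not given in the sources used here, and if they were split by the library in which a transcript was found, their medians, counts and dashes would carry that choice. Pearson's r was 0.77, 0.75 and 0.68 within series A, B and C, and Spearman's rho was 0.67, 0.75 and 0.62.

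**Figure D2:**
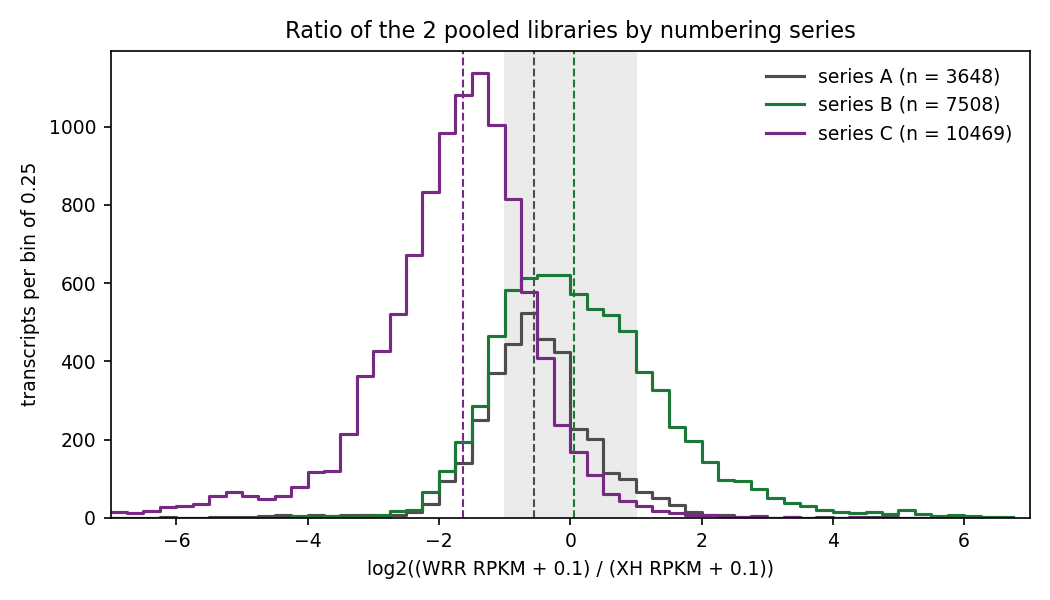
Number of transcripts per bin of the log2 ratio of WRR over XH RPKM (pseudocount 0.1) for the 3 numbering series, with values beyond the axis counted in the end bins, dashed lines at the medians and a grey band over ratios within 2-fold. The median of series C, -1.64, lies outside the band, while those of series A, -0.56, and series B, 0.057, lie inside it.

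Among transcripts read in both libraries, the 8 with the highest log2 ratios, ranked with the pseudocount, had ratios without it of 21.2 to 133. A 974-base transcript at chromosome 3, 2871214 to 2874719, had 326 reads (35.4 RPKM) in WRR and 2 reads (0.266 RPKM) in XH, a ratio of 133 (exact 95% interval 36.6 to 1104). A 205-base transcript at chromosome 7, 35067726 to 35067930, had 38.7 RPKM in WRR and 0.632 RPKM in XH, a ratio of 61.3 (10.7 to 2452). On chromosome 3, the transcript at 85951852 to 85959255 had a ratio of 53.9 (9.35 to 2162), and that at 74489507 to 74489725, with 37.7 RPKM in WRR and 1.78 RPKM in XH, a ratio of 21.2 (7.01 to 105). On chromosome 1, the transcript at 117520433 to 117522689 had a ratio of 49.8 (13.5 to 416) and that at 113642661 to 113645348 a ratio of 45.3 (12.3 to 379). The transcript at chromosome 2, 67472222 to 67472492, had 13.7 RPKM in WRR and 0.478 RPKM in XH, a ratio of 28.6 (4.81 to 1161). The eighth, on an unplaced scaffold, had a ratio of 35.1 (5.98 to 1419). All 8 had 1 to 3 reads in XH, so that the sizes are known only within these wide limits.

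Of the 8 transcripts with the lowest log2 ratios on the same scale, 6 lay on unplaced scaffolds. This ranking passes over transcripts of low RPKM that have as large a ratio without the pseudocount. A 382-base transcript on one of them had 2960 reads (1004 RPKM) in XH and 30 reads (8.32 RPKM) in WRR, 121-fold higher in XH (84.4 to 179). The other 5 were 46.2-fold to 99.1-fold higher in XH, with 1 to 4 reads in WRR and lower interval bounds of 14.2 to 22.7. The 371-base transcript at chromosome 2, 119205001 to 119205371, had 15.7 RPKM in XH and 0.285 RPKM in WRR, 55.1-fold higher in XH (9.39 to 2223). The 266-base transcript at chromosome 1, 48674612 to 48674877, had 18.0 RPKM in XH and 0.398 RPKM in WRR, 45.3-fold higher in XH (7.64 to 1837). The named transcripts of both directions kept their sign relative to the median of all transcripts, which their choice as the most extreme made certain.

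A dash in 1 library with at least 0.5 RPKM in the other was found for 461 transcripts without WRR reads and 157 without XH reads. A 1399-base transcript at chromosome 4, 13706488 to 13707886, had 610 reads (56.5 RPKM) over 99.6% of its length in XH and a dash in WRR. It was at least 249-fold higher in XH against the floor of 3 reads per library, and the exact 95% lower bound was 202-fold. The transcript at chromosome 1, 162396146 to 162396450, with 51.4 RPKM in XH, was at least 49.4-fold higher there (exact lower bound 39.5), and that at chromosome 1, 141598775 to 141598979, with 63.9 RPKM in XH, at least 41.2-fold (32.9). In the other direction, a 626-base transcript whose interval spans 26537 bp of chromosome 2, 55910590 to 55937126, had 77 reads (13.0 RPKM) in WRR and a dash in XH, at least 21.0-fold higher in WRR (exact lower bound 16.6). The transcripts at chromosome 3, 85960518 to 85961007, and chromosome 3, 76874939 to 76875597, had 9.51 and 9.47 RPKM in WRR and were at least 12.0-fold and 5.99-fold higher there (9.34 and 4.48). Few dashes stood against many reads. Of all 544 dashes in WRR, 8 had at least 50 reads in XH (median 15), and of all 296 in XH, 2 had at least 50 reads in WRR (median 4). Series C held 504 of the dashes in WRR and series B 254 of those in XH.

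Chromosomes of different size differed in the ratio. On chromosomes 1-5, the largest of the numbered ones, the median log2 ratio was -1.05 (95% interval -1.08 to -1.02, 11807 transcripts). There, 841 transcripts were at least 2-fold higher in WRR and 6118 in XH. On chromosomes 11-28 it was -0.51 (-0.55 to -0.46, 4118 transcripts), with 590 and 1411. Chromosomes 6-10 lay between them at -0.92 (-0.97 to -0.87), and unplaced scaffolds at -0.20 (-0.36 to -0.080). Relative to the median of all transcripts these values were -0.13 for chromosomes 1-5, 0.41 for chromosomes 11-28 and 0.72 for unplaced scaffolds. Against 10000 random sets matched on mean RPKM, chromosomes 11-28 lay above all (range -1.02 to -0.84) and chromosomes 1-5 below all (-0.96 to -0.89). With numbering series and length matched as well, both still lay outside the range, which was -0.81 to -0.69 for chromosomes 11-28 and -1.02 to -0.97 for chromosomes 1-5. Chromosomes 6-10 lay at percentile 41.2 of the sets matched on expression and at 0.31 of the full match. Their median was then -0.047 from that of the matched sets, against -0.051 for chromosomes 1-5 and 0.24 for chromosomes 11-28. The random sets could hold members of the class itself, and chromosomes 1-5 made up 11807 of the 21625 transcripts, against 3628 for chromosomes 6-10. The distance of chromosomes 1-5 is therefore understated more, and the 2 distances cannot be compared directly. Within the series, the medians of chromosomes 1-5 and 11-28 were -0.66 and -0.35 in A, -0.088 and 0.37 in B, and -1.70 and -1.39 in C.

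Chromosome 25 had the highest median among the chromosomes with at least 20 transcripts, 0.75 (0.26 to 1.14, 48 transcripts), followed by chromosome 27 with 0.27 (-0.048 to 0.73, 94 transcripts). Across the 28 numbered autosomes, which are not replicates, larger chromosomes had lower medians, with Pearson's r = -0.62 against the logarithm of size and Spearman's rho = -0.76. With each series centred on its own median, r was -0.36 and rho was -0.69. Chromosome 16, with 20 transcripts and a median of -1.03, departed from this order. Without chromosomes 16 and 1, the 2 farthest from the median on the logarithmic scale of size, r was -0.84 as deposited and -0.82 within series, and this pair includes the chromosome that departed from the order.

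**Figure D3:**
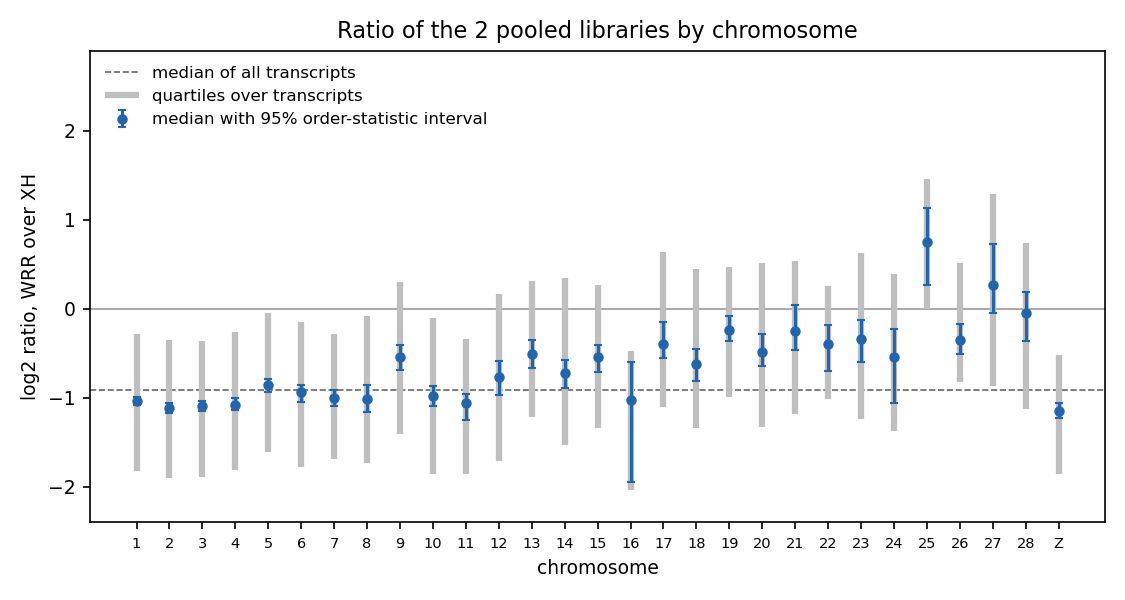
Median log2 ratio of WRR over XH RPKM for each numbered chromosome and Z (points), with 95% order-statistic intervals (thin bars) and quartiles over transcripts (grey bars), and a dashed line at the median of all transcripts, -0.92. Chromosomes 1-4, 6-8, 10, 11, 16 and Z lie below the dashed line, and chromosome 25 lies highest at 0.75.

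The W chromosome bears on the labelled sex, since both pools were made from hens, which carry a Z and a W, and says nothing of which library is of which strain. All 80 transcripts of W and its scaffolds had reads in both libraries, with 582 reads per M reads in WRR (exact 95% interval 567 to 597) and 771 in XH (752 to 791). The median log2 ratio of W was -0.58 (-1.03 to -0.24), or 0.34 relative to all transcripts. It lay at percentile 97.65 of the sets matched on expression and at 99.91 of those also matched on series and length. On Z the median was -1.15 (-1.23 to -1.06, 845 transcripts), or -0.24 relative to all transcripts, with 29 transcripts at least 2-fold higher in WRR and 478 in XH. The Z median lay below all 10000 sets matched on expression and at percentile 0.03 of those also matched on series and length. Chromosomes 2, 3 and 4 had medians near it, of -1.11, -1.09 and -1.08. Z carried 10.3 listed transcripts per Mb, against 19.8 on chromosomes 1-5 and 24.3 on chromosomes 11-28.

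Gapped transcripts, whose genomic interval was longer than the transcript, differed from contiguous ones. The 1028 gapped transcripts past the filter had a median log2 ratio of 0.053 (-0.063 to 0.18), with 269 at least 2-fold higher in WRR and 237 in XH. The 20597 contiguous transcripts had a median of -0.95 (-0.97 to -0.93), with 1774 and 9900. Relative to all transcripts these medians were 0.97 and -0.033. Gapped transcripts lay above all random sets matched on expression (-1.02 to -0.71) and above all those also matched on series and length (-0.65 to -0.38). Their median and that of contiguous transcripts were 0.052 and -0.59 in series A, 0.83 and 0.0077 in series B, and -1.12 and -1.65 in series C. Neither draw matched on chromosome class, and 17.4% of transcripts on unplaced scaffolds were gapped, against 4.75% of all. Without unplaced scaffolds the 2 medians in series A were -0.24 and -0.61.

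Short and long transcripts differed within the numbering series, and the order in series A and B was opposite to that of the pooled medians. In series A the median log2 ratio was 0.33 (95% interval 0.10 to 0.53) under 500 bases, -0.51 from 500 to below 2000 bases and -0.74 (-0.79 to -0.70) from 2000 bases on. In series B these medians were 0.29 (0.22 to 0.38), 0.080 and -0.66 (-0.71 to -0.58). In series C the order was that of the pooled medians, with -1.78 (-1.83 to -1.71), -1.62 and -1.56 (-1.62 to -1.46). Over all transcripts the medians were -0.95, -0.92 and -0.85 in the same order. The longest class lay at percentile 53.4 of sets matched on expression and below all 10000 sets also matched on series (-0.81 to -0.67). The shortest class lay below all sets matched on expression (-0.88 to -0.76) and at percentile 19.9 of those also matched on series. The middle class lay above all sets of the first match and at percentile 99.9 of the second. As for gapped transcripts, chromosome class was not matched. Transcripts on unplaced scaffolds had a median length of 697 bases, against 841 for all past the filter. Their median log2 ratios were -0.0097, 1.14 and -1.46 in series A, B and C. Whether they account for part of the order by length was not tested.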

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

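The settings by numbering series, the scaling to listed reads, the totals without the 10 transcripts of most reads, TMM, DESeq2 size factors and the minimum of 20 reads were chosen after the data had been seen. No paired analysis was possible because each strain has 1 pooled library, and for the same reason none could be left out. The neighbour gene lists were not run under any setting. The balance of directions moved with the scaling. The number at least 2-fold higher in WRR, 2043 as deposited, was 4813 when centred, 4369 after quantile normalization, 4627 with TMM and 4799 with size factors. The number higher in XH, 10137, was 4396, 4248, 4593 and 4417 in that order. These 4 settings bring the split near even by their construction. XH stayed ahead under the 2 others, with 2839 higher in WRR and 7807 in XH when scaled to listed reads, and 2150 and 9804 with totals without the top 10. These 2 are weak checks of the direction. Their log2 shifts were -0.32 and -0.046 in that order, against -0.87 for TMM and -0.91 for size factors. Listed reads also give weight to the most abundant transcripts. The median log2 ratio, -0.92, was -0.12 after quantile normalization, -0.043 with TMM, -0.0047 with size factors, -0.59 scaled to listed reads and -0.87 with totals without the top 10. Centring, quantile normalization, TMM and size factors assume that most transcripts do not differ or that distributions are alike. The median was -0.93 with a pseudocount of 0.01 RPKM, -0.73 with 1 RPKM, -0.82 with the filter in both libraries and -0.87 with at least 20 reads in a library. A pseudocount of 1 RPKM gave 1326 higher in WRR. At 4-fold, 686 were higher in WRR and 4008 in XH. By series, 188 (A) and 80 (C) were higher in WRR, 970 (A) and 1196 (B) were higher in XH, and the median was -0.56 in A, 0.057 in B, a reversed sign, and -1.64 in C. Pearson's r, 0.57, was 0.60 without a filter and 0.77, 0.75 and 0.68 in A, B and C. Spearman's rho, 0.55, was 0.57 without a filter and 0.67, 0.75 and 0.62. Without a minimum, 296 rather than 157 transcripts had a dash in XH. With a pseudocount of 1 RPKM the medians of chromosomes 1-5, 6-10, 11-28 and Z were -0.83, -0.75, -0.41 and -0.95, those of the length classes from short to long -0.83, -0.71 and -0.72, and that of contiguous transcripts -0.76. Centring gave -0.13, -0.0011 and -0.24 for chromosomes 1-5, 6-10 and Z, and reversed chromosomes 11-28 to 0.41, W to 0.34 and unplaced scaffolds to 0.72. Of the single transcripts named, those on an unplaced scaffold and on chromosome 7 among the most abundant reversed under quantile normalization, to -0.45 and -0.40. Another 21 values of named transcripts moved without a change of sign, and 85 stayed within their counting interval. Of the values for sets of transcripts, 39 stayed within their interval or within 1.5 times the count. Apart from the changes that follow from how a setting is built, the cause was not tested. Depth limits folds that rest on 1 to 3 reads.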

Other observations

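All tests in this part were chosen after the results they bear on had been seen. Neighbouring transcripts had like ratios. In 2 windows the median lay above all shuffles described below, but in 1 of these the ratio of summed reads was 1.09 (0.897 to 1.32). Among 1086 windows of 100 kb with at least 6 transcripts, with each series centred on its own median, the highest window median lay on chromosome 3 between 85903963 and 85982651. Its 14 transcripts were all at least 2-fold higher in WRR, with 490 reads there and 19 in XH, a ratio of 21.1 (exact 95% interval 13.3 to 35.3). All 14 were of series B. It holds 2 of the transcripts named in the results, those at 85951852 and 85960518. The interval of a further transcript, 85945599 to 85982651, encloses both, so the 14 are not known to be separate units. Levels were low, with 2.22 to 9.51 RPKM in WRR. Spearman's rho of the series-centred log2 ratios of adjacent transcripts was 0.40 for gaps under 1 kb, 0.31 for 1 to 5 kb, 0.17 for 5 to 20 kb, 0.16 for 20 to 100 kb and 0.044 for wider gaps.

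In the other direction, the lowest window median with the series centred was -2.04, on chromosome 2 between 147144612 and 147196284, where all 6 transcripts, each of series C, were at least 2-fold higher in XH, with 116 reads in XH and 15 in WRR. Among windows with at least 20 transcripts the lowest, -1.61, lay on chromosome 2 between 129000714 and 129096022, and 3 smaller windows lay below it. It held 23 transcripts, of which 20 were at least 2-fold higher in XH and 1 in WRR. It had 3920 reads in XH and 539 in WRR, 8.90-fold higher in XH (8.13 to 9.76), and 13 of its transcripts were of series C. A 2336-base transcript there, at 129040553 to 129042888, of series B, had 70.1 RPKM in XH and 3.99 RPKM in WRR, 17.6-fold higher in XH (14.2 to 22.1). In 200 shuffles of the values within the series the lowest window median was -2.63, and none of the 1086 windows lay below it, so neither of these windows was beyond the shuffles. Windows of all sizes entered that range, and it was not drawn for windows of 23 transcripts alone.

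For the chromosome 3 region, counting error would need an interval of the ratio that includes 2, and its lower bound was 13.3, or 8.95 at a level that allows for the choice among 1086 windows. Chance placement of unrelated transcripts is argued against by 200 shuffles of the values within the series, whose highest window median was 2.75 against 4.58 observed. The shuffles treated each transcript as a separate unit, and whether the 14 are parts of fewer transcripts was not tested. A second window above that level, with a median of 3.30 over 6 transcripts of a scaffold assigned to chromosome 2, had 4 transcripts at least 2-fold higher in WRR and 1 in XH, and a ratio of summed reads of 1.09 (0.897 to 1.32). A sequence difference between the strains that lowers mapping in XH cannot be told apart from lower transcription there, since both give 14 of 14 transcripts higher in WRR and the reads were not used here. A choice of series B transcripts by the library in which they were found, a difference between the strains, or one carried by single birds of a pool stays open as untested.

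The higher RPKM of most transcripts in XH was the second pattern weighed, with the deposited totals taken as given. The order of the serial numbers may come from transcripts found in WRR (series B) and in XH (series C), a hypothesis for which the labels hold no record. At the deposited totals, series C as the whole cause is argued against by the median of series A, -0.56, while a choice by library within series A stays open. This argument depends on the scaling, since series A lay at 0.36 relative to the median of all transcripts. Series B, with a median of 0.057, did not share the direction. Series C held 7971 of the 10137 transcripts at least 2-fold higher in XH. Were it a constant amount of genomic DNA reads per base in XH, the 0.587 RPKM by which XH exceeded WRR in the lowest expression decile of contiguous series A transcripts would predict -0.030 in the top decile, and the value was -0.37 (95% interval -0.57 to -0.18). More unspliced RNA in the XH pool is a candidate explanation. Gapped transcripts of series A outside unplaced scaffolds had a median 0.37 above that of contiguous ones (-0.24 and -0.61, with intervals apart), found and tested on the same data. No exon structure was at hand, so a gap is not shown to mark splicing. Chromosome class was not matched. Of transcripts past the filter, 6.29% on chromosomes 11-28 and 3.02% on chromosomes 1-5 were gapped, and their medians in series A were -0.35 and -0.66 in that order. Part of the 0.37 may therefore go with the trend with chromosome size, and how much was not computed. The gapped median of -0.24 (-0.42 to -0.13) lay above the -0.35 of chromosomes 11-28 (-0.41 to -0.28), although these intervals overlap. A strain difference stays open as untested, since 1 pool per strain leaves it inseparable from the preparation and scaling of the library.

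The trend with chromosome size was the third pattern. A mix of expression level, numbering series and length is argued against as its whole cause by the median of chromosomes 11-28, -0.51, against a range of -0.81 to -0.69 in matched sets. Small chicken chromosomes are known to be richer in GC than large ones, so a different response of the libraries to base composition is a candidate explanation. It cannot be told apart from a difference between the strains, because no base composition was used here, and the Spearman's rho of -0.76 with chromosome size goes with either.

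A 3030-base transcript at chromosome 1, 179739071 to 179743316, had 550 RPKM from 15747 reads in WRR and 186 RPKM from 4346 reads in XH, with 24.95% of its length covered in WRR and 26.7% in XH.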
